A study of Mus musculus with 20 samples.

How the data were processed

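The series holds 20 samples of mouse embryonic stem cells grown with LIF, CHIR99021 and PD0325901, 10 of them m6A immunoprecipitations with a peak list each and 10 of them inputs, which were not analysed here. Per the labels' protocols, RNA of the chromatin-associated fraction was depleted of ribosomal RNA, mixed with the control RNA of an m6A enrichment kit, fragmented, immunoprecipitated with that kit and sequenced from stranded total RNA libraries. Per the submitters' processing notes, CASAVA, Trimmomatic 0.38, HISAT2 2.1.0, MACS2 and the mm10 genome build were used. The version of MACS2, its command line, and whether each immunoprecipitation was called against its own input were not given in the sources used here.

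The deposited peak lists are in narrowPeak format. Peaks were called per library and per strand, by the names and the strand given in the files, and no list pooled libraries. The authors' values for each peak are a display score, a fold enrichment over background at the summit (a ratio), the −log10 of the p-value and of the q-value, and the position of the summit. By the values, the lists were limited to peaks of at least 150 bp and a −log10 q of at least 2.0. Fold enrichment was used only to describe, rank or filter peaks within a list, since a fold measured in different libraries carries no common scale. The folds of the control RNA are given side by side as values only.

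A peak list holds no read counts, and the number of reads per library was not given in the sources used here. For 4000 peaks per strand and library, the deposited fold enrichment and p-value were solved for a Poisson background and pile-up, and 100% matched a whole number of reads within 0.002 on the −log10 scale. The most common background, taken as a relative measure of depth, was 16.38 and 18.15 reads in the Mettl3 controls, 16.28 and 16.49 in KO1, 16.12 and 14.92 in KO2, 17.77 and 15.69 in the Ythdc1 controls, and 20.03 and 19.27 in the cKO, on the plus strand. Whether it follows the total reads was not tested, and it may reflect the input where one was used in peak calling. A deeper library can show weaker peaks, so absence from a list means that no peak was called at that depth, not that the RNA carried no m6A. Presence in a list in turn does not measure how much m6A the RNA carried.

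Libraries were grouped by the labels' titles. Peaks on chromosomes 1 to 19, X, Y and M were used, and 17 to 35 peaks per library on other contigs were left out of the comparisons. For each comparison the peaks of all its libraries were merged per strand into regions where they overlapped by at least 1 bp. A region counted as lost when it had a peak in both controls and in no knockout library, as kept when it had a peak in every library, and as gained when it had a peak in every knockout library and in neither control. Regions and summits were annotated with GENCODE M21 (GRCm38, the assembly of mm10), the 55450 genes and 81033 basic transcripts on these chromosomes. A summit was assigned to the first class that applied. First came mitochondrial, and then, on its own strand, 3' UTR, coding exon, 5' UTR, non-coding exon and intron. Last came antisense to a gene, promoter-proximal (within 2 kb upstream of a transcription start on either strand) and intergenic. The plan had merged regions without regard to strand and searched motifs on either strand. Merging per strand, the antisense class and the search on the sense strand depart from it and were chosen once the lists proved to be stranded. Motifs were searched within 50 nt of exonic summits on the sense strand of the transcript, with windows shifted by 1 kb as background. No genome sequence was used here, so intronic and intergenic motifs and the planned share of peaks in repeats were not analysed here.

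Per-library summaries were compared with exact permutation tests over all splits of the libraries, two-sided for differences of means and one-sided for counts of lost and gained regions. With 2 against 4 libraries there are 15 splits and with 2 against 2 there are 6. Loss by class and by height was given per knockout library. Height was the smaller within-list percentile of fold enrichment in the 2 controls, in 5 equal bins. For 13 gene lists, the share of genes with a control region that lost all of them was compared with all other such genes by Fisher's exact test with Benjamini-Hochberg adjustment over the lists, and with 10000 random gene lists of the same size matched on height bin. The bin of a gene was the highest among its control regions, and the number of regions per gene was not matched. Genes are not replicates, so these tests describe these libraries. Wilson intervals at 95% cover counting error only. The pattern that defined the histone list also took 5 genes outside the replication-dependent family, and the list was counted again with symbols that start with Hist. Genes of multicopy families, such as histones, Zscan4 and many zinc finger genes, share sequence with near-identical copies, and how the aligner placed such reads was not given in the sources used here.

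Apart from the use of strand, the groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named, per comparison, the genes with the 10 strongest lost, 5 strongest gained and 5 strongest kept regions, up to 2 lost and 2 kept members of each list, and the targeted genes, leaving out unnamed gene models and pseudogenes. Members named from outside the replication-dependent histone family and another kept list member are not reported here. The alternatives were a −log10 q of at least 5, a fold enrichment of at least 4, the same number of peaks from each library, an overlap of at least 50%, summits within 100 bp, a replicate block, leaving out each library, each Mettl3 knockout line alone, exon overlap for gene lists, and a looser rule for lost genes. The narrower histone list was added after the data were seen, and lost and gained regions were also counted with the strand ignored, as first planned.

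The steps were tested on simulated data. Among 20000 simulated regions per comparison, 100% of 200 regions set as lost and 100% of 200 set as gained were recovered. Among 10000 simulated genes, 100% of lists of 30 genes with a planted loss were called and 1.5% of lists without one. The simulated regions were removed outright, without detection error, and the planted loss was large and called without adjustment over lists. These simulations check the code and do not measure the power for the real lists. Peaks found again between a pair of libraries (39465) and merged regions (51928) were the same in number with bedtools and with separate code. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Matplotlib 3.10.9 and bedtools 2.31.1 were used.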

Results

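The series profiled N6-methyladenosine (m6A), the most common internal modification of messenger RNA, in the chromatin-associated RNA of C57BL/6 mouse embryonic stem cells. RNA was taken from the chromatin fraction, which is rich in nascent and retained nuclear transcripts, depleted of ribosomal RNA, fragmented and pulled down with an m6A antibody. Mettl3, the catalytic subunit of the nuclear m6A methyltransferase, was knocked out in the lines KO1 and KO2. Ythdc1, the nuclear protein that reads m6A, was removed conditionally (cKO). Each knockout was set against its own control. The 5 groups held 2 immunoprecipitated libraries each, 10 libraries in all, and the 10 matching input samples were not analysed here. Whether the libraries of a group came from separate cultures was not stated, so the p-values measure only the spread between these libraries, which may be technical.

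Every library gave a list of m6A peaks, called separately on each strand. The Mettl3 control libraries held 45292 and 46735 peaks, the KO1 libraries 40959 and 41004, and the KO2 libraries 44496 and 42804. The Ythdc1 control libraries held 43651 and 41941 peaks and the cKO libraries 45468 and 45599. Read depth was not used here. The genome-wide background pile-up behind the plus-strand peak p-values, taken here as a relative measure of depth that could not be checked against read totals, lay between 14.92 reads in KO2 replicate 2 and 20.03 reads in cKO replicate 1. Most peaks lay within genes. In the Mettl3 controls 38.2% ± 0.0298 of the peaks had their summit in an intron, 19.96% ± 0.191 in a coding exon, 10.7% ± 0.0136 in a 3' UTR and 15.7% ± 0.132 between genes (SD, n = 2). The Ythdc1 controls held more coding exon peaks, 27.7% ± 0.592, and fewer intergenic peaks, 10.2% ± 0.119 (SD, n = 2). GGAC, the core of the m6A consensus, stood within 50 nt of 51.3% ± 0.115 of the exonic summits of the Mettl3 controls, against 32.5% ± 0.216 in windows shifted by 1 kb (SD, n = 2). In the Mettl3 knockout libraries the shares were 48.9% ± 0.544 and 32.4% ± 0.104 (SD, n = 4). Most of the excess of GGAC was therefore present in the knockout lists too. Peaks were called within each library, so a kept peak or motif does not show how much m6A remained.

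**Figure D1:**
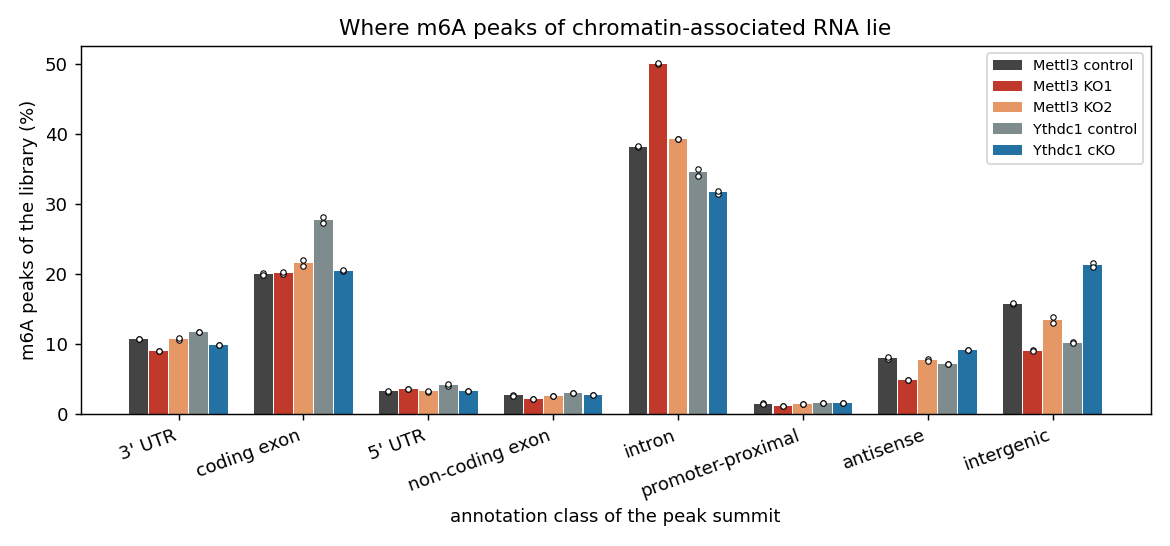
Share of each library's m6A peaks (y axis, percent) whose summit fell in each annotation class (x axis), with bars for the mean of the 2 libraries of a group and circles for the libraries. Intergenic peaks made up 21.3% of the peaks in the Ythdc1 cKO against 10.2% in its control, and 9.06% in Mettl3 KO1 against 15.7% in its control.

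The first comparison asked where m6A peaks were lost from chromatin-associated RNA without the methyltransferase. On Mettl3 itself, a region in a coding exon (chromosome 14, 52299727 to 52300096, minus strand, mm10) had a peak in both controls, at 6.15-fold and 5.06-fold enrichment. It had none in either KO1 library and peaks of 3.63-fold and 2.65-fold in the KO2 libraries. Ythdc1 kept its 6 control regions and gained an intron region (chromosome 5, 86819945 to 86820103, plus strand) with peaks of 2.59-fold to 3.47-fold in the 4 knockout libraries. A peak list does not measure the amount of a transcript, so this does not check the genotype of any library. Fold enrichments here and below are the authors' values for single peaks within a library's own list.

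Of the 38052 regions with a peak in both Mettl3 controls, 5001 (13.1%) had no peak in any of the 4 knockout libraries, and 21961 (57.7%) were kept in all 4. The lost regions touched 2006 genes, and 513 of the 10379 genes with a control region (4.94%) lost all of them. Peaks outside annotated genes and antisense to genes were missing most often. Per knockout library, 46.3% ± 9.85 of the intergenic and 44.3% ± 9.05 of the antisense control regions were absent, against 16.5% ± 2.45 of those in coding exons and 22.6% ± 1.36 of those in introns (SD, n = 4). Intergenic regions were absent more often than coding exon regions in 4 of 4 libraries, with the lowest intergenic value at 36.4% and the highest coding exon value at 18.96%. The classes were not matched on peak height, with which absence also varied, so an effect of class and one of peak height cannot be told apart here. A further 1081 regions were present in all 4 knockout libraries and in neither control, and 710 of these lay in introns.

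**Figure D2:**
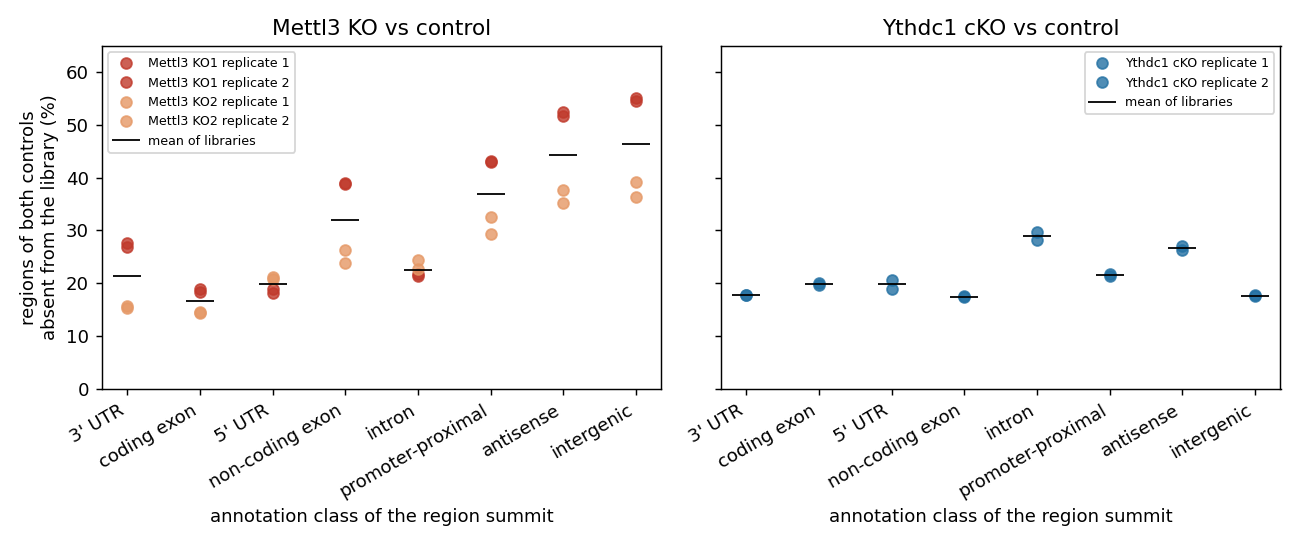
Share of the regions found in both controls that had no peak in a knockout library (y axis, percent), by annotation class (x axis), with a point per library and a line at the mean. In the Mettl3 knockouts intergenic and antisense regions were absent most often, with KO1 above KO2, and in the Ythdc1 cKO intron regions were, at 28.9%. The classes were not matched on peak height.

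The strongest lost regions lay in genes of several kinds. Ccdc80, which encodes an extracellular matrix protein, lost a 5' UTR region (chromosome 16, 45093901 to 45094323, plus strand) of 10.6-fold and 10.4-fold enrichment in the controls. Inhba, the activin beta A subunit, lost both of its regions, the stronger in a coding exon (chromosome 13, 16026298 to 16026772, plus strand) at 10.4-fold and 11.2-fold. Csf1, macrophage colony-stimulating factor, lost a coding exon region (chromosome 3, 107748500 to 107749072, minus strand) of 12.4-fold and 9.79-fold. Utf1, a chromatin-bound factor of undifferentiated embryonic stem cells, lost its only region, in a coding exon (chromosome 7, 139944093 to 139944291, plus strand), of 7.65-fold and 8.82-fold. Regions were also lost from the long non-coding RNA Platr31, from Ccser1, the galactosyltransferase gene B4galt2, the peptidase genes Dpp9 and Mipep, and Immp2l, a mitochondrial peptidase subunit, where 4 of 27 control regions were lost and 14 kept. Inhba, Platr31, Utf1 and B4galt2 lost every control region. Ccdc80 and Csf1 lost 1 of 2 each and Ccser1 3 of 6, and each of them had 0 kept regions. Dpp9 kept 2 of 6 and Mipep 2 of 4. Without the input libraries, a lower amount of a transcript and a loss of m6A from it cannot be told apart. The strongest gained region lay in the 3' UTR of Grk3, a kinase of G protein-coupled receptors (chromosome 5, 112960412 to 112960692, minus strand), at 10.3-fold to 15.4-fold. Introns of Pknox2, Mindy4, Mcc and Slc9b1 held the next 4. The strongest kept regions lay in the deubiquitinase gene Usp35, in Brwd3, Trmt13 and Pms2, a mismatch repair gene, and in an intron of Rerg. The Usp35 region (chromosome 7, 97311786 to 97312432, minus strand, coding exon) had 29.2-fold and 28.2-fold enrichment in the controls and 25.5-fold to 33.5-fold in the knockouts.

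Among 13 gene lists, 2 differed from the other genes in how many members lost every control region. Of the 8 fibroblast markers with a control region, 4 lost all of it (adjusted p = 0.0027, Fisher's exact test, Benjamini-Hochberg over the lists), more than 99.9% of random lists matched on peak height. These were the collagen genes Col1a1, Col1a2 and Col5a2 and the collagen cross-linking enzyme gene Lox, the last 2 named after their values were seen. The Col1a1 region (chromosome 11, 94951387 to 94951818, plus strand) had 3.54-fold and 4.32-fold enrichment in the controls. Col5a1 and Pdgfrb kept theirs. The 8 markers held 9 control regions, and the random lists were not matched on the number of regions per gene. Fibroblasts are commonly used as feeder cells for stem cell cultures, and the growth conditions as described do not mention them. Numbered zinc finger genes lost all control regions less often than other genes, in 4 of 332 (1.205%; adjusted p = 0.0027, Fisher's exact test). The 4, named after their values were seen, were Zfp352, Zfp362, Zfp512 and Zfp672. Among the others, Zfp943 lost 3 of 12 regions and Zfp977 1 of 2, and Zfp973 and Zfp62 kept regions of 8.36-fold or more.

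The other lists did not pass Fisher's exact test. Of 14 genes of the 2-cell-like state, a rare state of stem cell cultures, 3 lost every region (adjusted p = 0.126, Fisher's exact test), although this share stood at percentile 99.4 of random lists matched on peak height, which lost 3.91% on average. These were Tcstv3, Zfp352 and, named after its values were seen, Usp17la. Zscan4b and Zscan4e kept a region each, with enrichment of 2.65-fold or more in the knockouts. When a loss in 3 of 4 knockout libraries was enough, 35.7% of the list lost every region (adjusted p = 0.0146, Fisher's exact test). Members of this list have near-identical copies, so their reads may have been split or shared. Of 24 pluripotency genes only Utf1 lost every region, Nr5a2 lost 1 of 8, and Fgf4 kept its only region. None of the 18 genes for m6A writers, readers and erasers lost every region, although Wtap, a writer subunit, lost 1 of 3 while Cbll1 and Igf2bp3 kept theirs. None of 15 nuclear RNA decay genes did either, with Zc3h18 losing 1 of 6 regions, Zfc3h1 keeping 8 of 9 and Exosc5 1 of 3. Nor did any of 34 chromatin regulators, among which Setdb1 and Kdm5a lost 1 region each while Ehmt1 and Setd2 kept regions of 7.69-fold or more. Of 20 chromatin-associated and imprinted long non-coding RNAs, Xist lost 1 of 2 regions and Meg3 2 of 6, and Tug1 kept its 4 and Dleu2 3 of 6. The counts were 0 of 8 differentiation markers, with Nodal and Nes losing 1 of 3 regions each and Lama1 keeping 6 of 8, and 1 of 16 immediate early genes, which was Fosl2 while Jun and Spry2 kept theirs. They were 0 of 16 ribosomal protein genes, Rpl30 and Rpl10l among the kept, 0 of 24 genes of the histone list, Hist1h2af and Hist1h2bg among the kept, and 0 of 6 mitochondrially encoded genes, mt-Nd4 and mt-Nd5 among the kept. Against random lists matched on peak height, which lost 13.5% on average, the histone list stood at percentile 1.47, the zinc finger list stood at 1.455 of its own, and the lists not given a percentile so far lay between 4.295 and 78.6.

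The libraries covered 19.2 Mb ± 0.627 in the Mettl3 controls (SD, n = 2) and 15.997 Mb ± 0.704 in the knockouts (SD, n = 4). This difference had a two-sided exact permutation p of 0.0667, the smallest that the 15 splits of 6 libraries into 2 and 4 allow, so no p under 0.05 was possible. The count of lost regions reached the same one-sided exact permutation p of 0.0667, and the count of gained regions gave 0.133. The 15 splits treat the 4 knockout libraries as exchangeable, although they come from 2 lines. Permutation p and SD over these 4 libraries therefore overstate the replication. With the KO1 pair split off, 2022 regions were found only in that pair and 2481 only in all other libraries. With the KO2 pair the counts were 3155 and 1015. The control pair gave 5001 lost, above both lines, and 1081 gained, between the lines. The control libraries found 85.4% ± 2.48 of each other's peaks (SD, 2 ordered pairs), and the knockout libraries held 67.1% ± 2.74 of the control peaks (SD, 8 ordered pairs; exact permutation p = 0.0667). Weak regions were absent more often than strong ones. From the weakest to the strongest of 5 equal bins of control peak height, 38.3%, 42.2%, 32.8%, 16.8% and 4.27% of regions were absent per knockout library (n = 4). None of the 9 class shares passed, with adjusted exact permutation p of 0.24 or more, the intergenic share being 15.7% ± 0.132 in the controls (n = 2) and 11.2% ± 2.53 in the knockouts (n = 4). Lost and kept exonic regions held GGAC at similar rates, 52.4% (Wilson 95% interval 49.6 to 55.3) and 51.9% (50.9 to 52.9), and gained regions at 38.5% (31.9 to 45.5). A DRACH site, the m6A consensus, lay near 92.8% ± 0.00155 of exonic control summits (SD, n = 2) and 91.3% ± 0.468 of knockout summits (SD, n = 4), with 86.9% to 87.6% in shifted windows. Without control replicate 1 the count of lost regions was 8606 and without control replicate 2 it was 7619, and the gained counts were 1834 and 1964.

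The labels name KO1 and KO2 as separate knockouts of Mettl3, which allowed a comparison of their losses. KO1 lost 9203 control regions from both of its libraries and KO2 6999, and 5001 were lost in all 4. Of the intergenic control regions 48.9% were lost from both KO1 libraries and 30.7% from both KO2 libraries. Intron regions were lost at 16.3% and 17.2%. Intron peaks made up 50.1% ± 0.0249 of the KO1 libraries, 39.4% ± 0.00619 of the KO2 libraries and 38.2% ± 0.0298 of the controls (SD, n = 2). Independent lists of these sizes would share 1692.7 regions, or 2208.8 within bins of peak height. Unchanged libraries simulated against the same controls shared 62.7 on average and 89 at most. The simulation held only the error between libraries of the control group, so it cannot show what a difference between lines would give. For scale, 2022 regions had a peak in both KO1 libraries and no other library of the comparison, and 3155 in both KO2 libraries and no other. The controls are shared and too few to split, so part of the excess may come from them.

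The second comparison asked how the m6A peaks of chromatin-associated RNA differ without the reader Ythdc1. On Ythdc1 itself, 6 of 7 control regions were kept in both cKO libraries, among them a coding exon region (chromosome 5, 86835649 to 86836084, plus strand) of 4.01-fold and 4.58-fold enrichment in the controls and 4.66-fold and 5.01-fold in the cKO. An intron region (chromosome 5, 86819945 to 86820108) of 3.04-fold and 3.36-fold enrichment in the controls was lost, at the place where the Mettl3 knockouts gained one and the Mettl3 controls had none. Mettl3 lost 1 of 2 control regions (chromosome 14, 52300276 to 52300498, minus strand; 4.73-fold and 5.58-fold in the controls), and the other had a peak in 1 of the 2 cKO libraries. The conditional deletion may leave part of the transcript, and peaks do not measure its amount, so this does not check the genotype either.

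Intergenic peaks made up 10.2% ± 0.119 of the lists in the Ythdc1 controls and 21.3% ± 0.427 in the cKO, and coding exon peaks 27.7% ± 0.592 and 20.5% ± 0.134 (SD, n = 2). Among all 10 libraries the cKO stood apart in the intergenic share, with 21.63% and 21.03% against 8.997% to 15.8% in the others, and the Ythdc1 controls stood apart in coding exon peaks, with 11808 and 11924 against 8200 to 9428 in the others. Of the 38358 regions found in both cKO libraries, 10731 (28.0%) had no peak in either control, and 4994 of these were intergenic, which is 60.6% of the 8245 intergenic cKO regions. Of the antisense cKO regions 44.1% were gained, of the intron regions 26.2% and of the coding exon regions 5.67%. Of 34212 control regions 6119 (17.9%) were lost, 464 of them intergenic, and 24718 (72.2%) were kept. Absence per cKO library was 28.9% ± 1.17 for intron regions against 17.7% ± 0.106 for intergenic regions (SD, n = 2), again without matching the classes on peak height.

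Some genes held several gained regions. The strongest gained region lay in an intron of Fhit, a gene at a chromosomal fragile site (chromosome 14, 10489236 to 10490136, minus strand), at 14.9-fold and 14.3-fold enrichment, and Fhit held 29 gained regions beside 3 control regions. Tbx3os1, a long non-coding RNA next to Tbx3, gained 12 regions and Pde1c, a cyclic nucleotide phosphodiesterase gene, gained 8. The strongest in Tbx3os1 lay in an exon (chromosome 5, 119574651 to 119574986, minus strand) at 13.4-fold and 14.6-fold. Introns of the tetraspanin gene Tspan7 and of Ccdc50 held the other gained regions among the strongest 5. The strongest lost regions were led by the 3' UTRs of Lrrc15 (chromosome 16, 30271600 to 30271892, minus strand; 10.4-fold and 11.8-fold in the controls) and Rnf165, a ubiquitin ligase gene (chromosome 18, 77459805 to 77460310, minus strand; 10.2-fold and 11.9-fold). Prkcsh, the glucosidase II beta subunit, lost 6 of 8 control regions, and Stip1, a co-chaperone of Hsp70 and Hsp90, lost 3 of 6. Chga, which encodes chromogranin A, lost 2 of 3, and the calcium-binding protein gene S100a13 its only region. The others among the strongest 10 were Paip2b, Myh13, Trim33 and Zfp428. The strongest kept regions lay in Sox11, a transcription factor gene, and in Pik3ca, Cnnm3, Chd9 and Sash1. That of Sox11 (chromosome 12, 27341088 to 27342677, minus strand, coding exon) had 28.1-fold and 27.4-fold enrichment in the controls and 12.7-fold and 15.4-fold in the cKO.

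Ribosomal protein genes lost every control region in 14 of 38 cases, Rpl21 and Rpsa among them, while Rpl7a and Rpl30 kept theirs (adjusted p = 1.05e-05, Fisher's exact test). Their peaks were weak, and random lists matched on peak height lost 28.8% on average, so the list stood at percentile 86.7 of these. Numbered zinc finger genes again lost all regions less often, in 4 of 335 (1.19%; adjusted p = 3.48e-08, Fisher's exact test), below all 10000 matched lists. The 4, named after their values were seen, were Zfp119b, Zfp346, Zfp410 and Zfp512. Zfp428 lost 2 of 5 regions and Zfp131 1 of 4, and Zfp973 and Zfp513 kept regions of 13.7-fold or more. Both calls were made with Benjamini-Hochberg over the lists.

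The remaining lists did not pass at an adjusted p under 0.05. Lin28a, an RNA-binding protein of stem cells, and Dppa5a, named after its values were seen, lost every region among 26 pluripotency genes, Prdm14 lost 1 of 2, and Klf4 and Nr0b1 kept theirs. Of 19 writers, readers and erasers only the writer subunit gene Mettl14, named after its values were seen, lost every region. Virma lost 1 of 8 and Igf2bp1 2 of 4, and Ythdf3 kept all 5. Of 43 genes taken by the histone pattern 6 lost every region, Hist1h2ac among them, and Hist2h3c1 and Hist2h3c2 kept theirs. With symbols that start with Hist it was 5 of 40, a list not set against matched lists. The 6 of 43 are 13.95% against 27.8% on average in random lists matched on peak height, percentile 1.47 of these. Genes that lost every region numbered 0 of 35 chromatin regulators, although Chd7 lost 5 of 13 regions and Kdm5a 1 of 7, and Dnmt3a kept its strongest. They numbered 0 of 15 RNA decay genes, with Zfc3h1 losing 2 of 10 and Mtrex 1 of 3 while Zcchc8 kept both. They numbered 0 of 20 long non-coding RNAs, with Firre losing 3 of 7 and Pvt1 3 of 8 while Tug1 kept its 5 and Airn kept 7 and gained 10. Of 10 genes of the 2-cell-like state Tmem92 lost its only region, Zscan4e lost 1 of 2 and Zscan4f and Usp17lc kept a region. None of 8 differentiation markers lost every region, with Lefty1 losing 3 of 4 and Tfap2c 2 of 4 and Nes keeping both. The 4 fibroblast markers with a control region, Col5a1 and Pdgfrb among them, and the 11 immediate early genes, Jun and Jund among them, lost none entirely. No mitochondrially encoded gene had a region in both controls. The remaining lists other than the histone genes lay between percentiles 3.375 and 83.7 of their matched lists.

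The 6 splits of 4 libraries into 2 and 2 allow no p under 0.05. The gained count of 10731 gave a one-sided exact permutation p of 0.167, the smallest possible, and the lost count of 6119 gave 0.333, because the same split read the other way gives 10731. The share of intergenic peaks was 11.1 percentage points higher in the cKO, with a two-sided exact permutation p of 0.333, the smallest possible, and 0.375 after adjustment over the 9 classes. Control libraries found 84.1% ± 2.85 of each other's peaks (SD, 2 ordered pairs), and cKO libraries found 70.4% ± 1.12 of the control peaks (SD, 4 ordered pairs). Absence per cKO library was 42.9% in the weakest bin of peak height and 2.14% in the strongest (n = 2). GGAC lay near 45.7% of lost (Wilson 95% interval 43.8 to 47.7), 51.9% of kept (51.1 to 52.8) and 45.5% of gained exonic regions (42.4 to 48.6). With only peaks of at least 4-fold enrichment the lost count was 3942. Without control replicate 1 it was 9840 and without control replicate 2 it was 11011.

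The last comparison asked whether both knockouts removed the same regions. Of the 24366 regions present in all 4 control libraries, 1607 were lost from all Mettl3 knockout libraries and 1675 from both Ythdc1 cKO libraries. They shared 325, against 110 for independent lists, an odds ratio of 4.02 (Fisher's exact p = 1.70e-75 over regions, which are not replicates). Within bins of peak height the Mantel-Haenszel odds ratio was 2.56. Regions were not matched on annotation class or on how reliably they were detected, so part of the excess may come from these. Overlapping coding exon regions of Kdm5a, a histone demethylase gene (chromosome 6, 120412107 to 120412465, plus strand, in the Ythdc1 comparison), were lost in both, and the zinc finger gene Zfp512 lost its only region in both.

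The control lines themselves differed at least as much as a control and its knockout. The Jaccard index of covered bases was 0.742 between the Mettl3 controls and 0.721 between the Ythdc1 controls. It was 0.526 on average between Mettl3 and Ythdc1 controls, 0.540 between the Mettl3 controls and KO1, 0.569 between the Mettl3 controls and KO2, and 0.531 between the Ythdc1 controls and the cKO. The cKO libraries shared 0.539 with the Mettl3 controls.

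**Figure D3:**
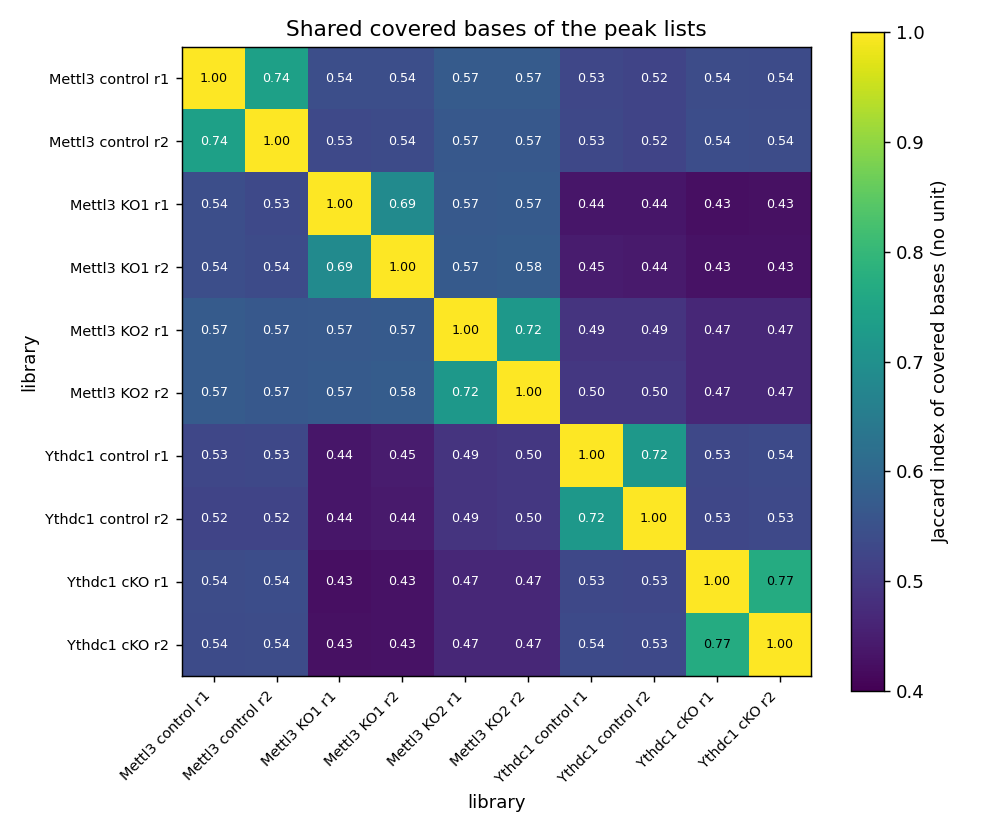
Jaccard index of covered bases (colour, no unit) for each pair of the 10 libraries (both axes), with the value in each square. Pairs from the same group lie between 0.687 and 0.769, and all other pairs lie at 0.575 or below.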

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

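The tests of the intergenic share of KO1 and KO2 were chosen after that pattern was noticed and before their own values were seen.

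The Mettl3 knockout lines lay on opposite sides of their control in 3 of 37 per-library summaries of the peak lists, with both libraries of each line beyond both controls. The number of genes with a peak was −884.5 in KO1 and 139 in KO2 relative to the control mean, the number of coding exon peaks was −907.5 and 231.5, and the median −log10 q was −2.73 and 2.20. The differences between the lines were not tested.

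The control RNA of the enrichment kit, which the comparisons did not use, gave a peak in every library. Its plus-strand enrichment was 22.5-fold and 23.3-fold in the KO2 libraries and 18.2-fold and 11.1-fold in the Mettl3 controls, and it was 12.5-fold and 12.3-fold in KO1, 17.4-fold and 18.0-fold in the Ythdc1 controls and 14.6-fold and 14.1-fold in the cKO. These folds carry no common scale, so no difference is read from them.

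KO1 had fewer intergenic peaks than KO2, 9.06% ± 0.0916 against 13.4% ± 0.569 of the list (SD, n = 2). With the 40959 strongest peaks of each library the gap was 4.33 percentage points, against 4.34 with all peaks, which argues against the length of the lists as its cause. Both KO1 libraries lay below both KO2 libraries on 20 of 20 chromosomes (1 to 19 and X), which argues against a different copy number of a few chromosomes. A difference between the lines in how much methyltransferase activity remained, in the RNA present or in handling may each account for the gap, and none of these was tested. Both lines share 1 control group, so line and preparation cannot be separated here.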

How the results depend on the processing

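Tests of regions merged per strand, in place of the planned merge without strand, and of the narrower histone list were chosen only after the data were seen. Of 389 comparisons of a result with an alternative, 372 kept their direction and size or call, 11 counts moved by over 1.5 times, 3 values reversed, 3 list calls were added and 0 were lost. No exact permutation test here could pass 0.05, so kept sides of that threshold say nothing about stability, and the cause was not tested unless stated. With KO1 alone 9274 regions were lost and 3959 gained, and with KO2 alone 7040 were lost and 5161 gained, since 2 libraries in place of 4 had to share a state (regions were merged again from the libraries of each setting). Leaving out a library moved the Mettl3 lost count between 5479 and 8606 and the gained count between 1451 and 1964 (8606 and 1834 without control replicate 1, 7619 and 1964 without control replicate 2), and the Ythdc1 lost count between 7706 and 11011 (9840 and 11011 without control replicate 1 and 2), because fewer libraries had to share a state. The Ythdc1 gained count was 11958 to 14454 in those settings. With peaks of at least 4-fold enrichment the Ythdc1 lost count was 3942, and the Mettl3 difference in the coding exon share reversed to −0.539 percentage points from 0.925. The Mettl3 difference in the 3' UTR share was 0.000117 with KO2 alone and −0.869 with both lines. The Ythdc1 difference in the promoter-proximal share ran from −0.0335 to 0.00932 when a library was left out, reversing without control replicate 1. The looser rule for lost genes raised the called lists from 2 to 4 for Ythdc1, adding chromatin regulators (0 of 35 lost, adjusted p = 0.0209, Fisher's exact test) and histone genes (13 of 43, adjusted p = 0.0209, not matched on height, while by the main rule the list lost less than matched lists, at percentile 1.47), and for Mettl3 it added the 2-cell-like state (35.7%, adjusted p = 0.0146). With the strand ignored, as first planned, 4843 regions were lost and 1052 gained for Mettl3, and 5869 and 10415 for Ythdc1, and with symbols that start with Hist 0 of 21 and 12.5% of 40 histone genes lost every region. The Mantel-Haenszel odds ratio of regions lost in both knockouts was 2.43 to 2.69 over the alternatives, and the intergenic share of the cKO stayed 10.8 to 12.8 percentage points above its control.

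The replicate numbers did not pair the libraries. Deviations of same-numbered libraries correlated at 0.00668, 0.00411 and 0.0118 between the Mettl3 groups and −0.000279 between the Ythdc1 groups over 87498 regions, and with the replicate number as a block 32 of 32 results kept their side, the Mettl3 lost count being 5001 with an exact permutation p of 0.111. The planned share of peaks in repeats was not run, because no genome sequence was used here. Incomplete detection limits every absence, since libraries of the same group did not find all of each other's peaks, 85.4% ± 2.48 in the Mettl3 controls and 84.1% ± 2.85 in the Ythdc1 controls (SD, 2 ordered pairs each). In the weakest of 5 bins by the height in Mettl3 control replicate 1, 71.7% of its regions had a peak in control replicate 2. Whether depth was the reason was not tested.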

Other observations

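In this part the tests of gained lists, of chromosome copies, of sensitive calling as the whole cause and of both explanations for the fibroblast markers were chosen only after the result was seen. The depth test was added after the sensitivity test had given an intermediate value and before its own value was seen.

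Genes of the mitochondrial chromosome stood out among the cKO gains. All 7 mitochondrially encoded genes with a region in the Ythdc1 comparison gained one (adjusted p = 9.62e-05, Fisher's exact test over 13 lists, against 18.5% of all genes). None of these genes had a region in both controls, so the test left little room for another outcome. The mitochondrial chromosome held 3 and 2 peaks in the Ythdc1 controls, 12 and 10 in the cKO and 10 to 12 in each Mettl3 library, so the Ythdc1 controls stood apart. None of 50 ribosomal protein genes gained a region (adjusted p = 0.000416, Fisher's exact test), and 1 of 54 genes of the histone list did (adjusted p = 0.00141). In the Mettl3 knockouts 9 of 355 numbered zinc finger genes gained a region, 2.54% against 6.29% of all genes (adjusted p = 0.0226, Fisher's exact test). The tests are over genes, which are not replicates, and genes were not matched on length or intron content. Of the gained cKO regions 3079 lay in introns and 464 in coding exons. Low shares of genes with a gain may therefore follow from gene structure, which was not tested.

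On the X chromosome 75.4% of the 712 intergenic cKO regions were gained, against 59.2% of the 7475 on the autosomes, and 60.5% against 43.5% of the antisense regions. The X held 1136 and 1053 peaks in the Ythdc1 controls, 1805 and 1785 in the cKO and 1184 to 1515 in the Mettl3 libraries. The Y held 46 and 48 peaks in the Ythdc1 controls, 94 and 96 in the cKO and 84 to 101 in the Mettl3 libraries, so there the Ythdc1 controls stood apart. Over all classes 51.3% of the cKO regions on the X and 49.3% of those on the Y were gained. The difference between X and autosomes was not tested.

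Of the 8245 intergenic regions found in both cKO libraries, 4994 were absent from both Ythdc1 controls. The gained share reached at least 50% of the genome-wide share on 20 of 20 chromosomes (1 to 19 and X), which argues against extra copies of a few chromosomes, and 62.1% ± 0.889 of intergenic cKO peaks of at least 4-fold enrichment were absent from a control library (SD, 4 pairs) against 9.15% of those of the control with the higher background in the other control, a ratio of 6.79 that argues against lower control depth as the whole cause if the background follows depth. With the same number of strongest peaks from each library the cKO share stayed 11.4 percentage points above its control. Trimming the cKO lists of 45468 and 45599 peaks to 41941 could not have closed the gap, whichever peaks were dropped. That value is therefore no test of more sensitive calling in the cKO as the whole cause. The median gained intergenic region stood at percentile 45.1 of its list (quartiles 27.6 and 63.2), between the 25 and 50 set as bounds. A part from more sensitive calling therefore cannot be told apart. A hypothesis is that intergenic RNA may accumulate on chromatin without Ythdc1, or carry more m6A, and without the input libraries these cannot be separated. A difference between the lines that is unrelated to Ythdc1 also stays open and untested.

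Of the fibroblast markers, Col1a1, Col1a2, Col5a2, Lox and Acta2 had peaks in both Mettl3 controls and in none of the 4 knockout libraries, and Tagln in 1 control, while Twist1 had the reverse, a peak in both KO2 libraries and in no other (Acta2, Tagln and Twist1 were named after their values were seen). The share of markers that lost all regions stood at percentile 99.9 of lists matched on height. This is the value that set the list apart, so it is no separate test of weak peaks as the cause. The matched lists did not match the number of regions per gene either. Of 20 markers 9 and 10 had a peak in the controls, 4, 3, 5 and 5 in the knockouts and 4, 5, 6 and 6 in the Ythdc1 libraries, a ratio of control to knockout means of 2.24, and peaks on both Col1a1 and Col1a2, which fibroblasts make in large amounts, were found together only in the Mettl3 controls among the 10 libraries, while Col3a1 and Dcn, also abundant in fibroblasts, had none in any. This is what fibroblast-like cells in the control cultures may give, but a loss of m6A from these RNAs would give it too, and without the input libraries the 2 cannot be told apart. Col5a1, Pdgfrb, Fbn1 and Loxl1 had peaks in both Ythdc1 controls as well, so part of the list is detected in other libraries of these cells.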
